A study of Mus musculus with 5 samples.

How the data were processed

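The series holds 5 RNA sequencing libraries of CD11b-positive forebrain cells from postnatal day 8 mice, 3 labelled Stat3 conditional knockout and 2 labelled control. Per the labels, tamoxifen was given daily from postnatal day 1 to 3, cells were enriched on a Percoll gradient and sorted, RNA with an integrity number over 8 was used, and 200 ng per sample went into a polyA library kit that does not mark strand. The controls lack the Cre allele. Loss of Stat3 therefore comes together with 1 disrupted copy of Cx3cr1, the presence of Cre and the DNA that flanks the insertion. Groups and replicate numbers came from the sample titles.

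Per the labels, 286 M reads of 40 bp were obtained over the series, of which 274 M (95%) aligned to GRCm38/mm10. The submitters' processing notes name TopHat2 2.0.13 and DESeq2, without the role or version of the latter. The read counter and the annotation are not given in the sources used here. The deposited table gives 1 value per gene and library on what was taken as a log2 scale, centred per gene on a value that is not part of it. That scale was inferred from the values, which run from -4.12 to 7.69. Of 23420 listed genes, 6974 were exactly 0 in all libraries, and 4483 followed 1 fixed pattern across libraries with a gene-specific size. A regularized log transform gives these shapes to genes with no reads, and it also shrinks differences of genes with few reads. Log2 differences are therefore likely understated for such genes. The depth per library is unknown, and no interval that needs counts is given. Small counts were common: 17.0% of tested genes had knockout replicate 1 above replicate 2 by at most 0.02, against 0.2% the other way, as equal small counts give.

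The value a gene takes at 0 reads was found from its fixed pattern, with a tolerance of 2% of the span. Genes at that value in 4 or 5 libraries, genes at 0 throughout and 27 names turned into dates by a spreadsheet were left out, so that tested genes lay above it in at least 2 libraries, the size of the smaller group. This left 9400 genes. A pair of libraries at that value is harder to recognise, so counts of genes at it in both controls are lower bounds. The filter was chosen after the values had been inspected and before the first fit. The bound on the span (0.1157) was tightened in 2 steps after results had been seen, because unrelated values had been taken for 0 reads. In all, 0 genes passed under each version of that rule.

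The planned test depended on the unit, and since the values were already log2 the main test was limma on the values as deposited (~ group, eBayes without trend or robust estimation), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per group are the mean ± SD, and SE and 95% intervals come from limma. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. Fry asks whether a list moves on balance in 1 direction and compares it with no other genes. R 4.3.3, limma 3.58.1, fgsea 1.28.0 (for its Reactome sets), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Replicates are separate pools of pups.

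The 24 lists were fixed before the data were examined, as were the rule for named genes and most alternatives. They cover JAK-STAT components, STAT3 target genes, homeostatic microglia, postnatal and disease-associated microglia, type I interferon response, inflammatory cytokines and NF-kB, trophic and anti-inflammatory factors, complement and phagocytosis, antigen presentation, cell cycle, immediate early and dissociation response, lipid and cholesterol metabolism, glycolysis and oxidative phosphorylation. The others are markers of border macrophages, monocytes, neutrophils, lymphocytes, neurons, astrocytes, oligodendrocyte lineage, endothelial cells, mural cells and fibroblasts, and red blood cells. The minimum of 3 tested members was set after list sizes and first results had been seen and left 21 lists.

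Named genes are Stat3 and Cx3cr1, 10 genes per direction with the smallest p where too few passed, provided the groups did not overlap, and the 2 members of each list with the smallest p. Clone names and sex-linked genes were left out of the 10, which passed over 2 names in each direction, and sex-linked genes are given per library. One result among the named genes is not reported here. The planned minimum level for named genes could not be applied, since the values hold no level. Coordinates come from GENCODE vM21 on GRCm38, counted from 1.

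The tests were tested on simulated data with the real genes' means and with spreads drawn at random from the distribution limma fitted to them. At this size limma found 0% of genes changed by 1 log2 unit, 25.4% of those changed by 2 and 77.3% of those changed by 3 among 9400 genes, with 4.2% of calls unchanged. Camera called 100% of lists of 35 genes shifted by 0.7 and 3% of unshifted ones at an unadjusted p under 0.05. These simulated genes were independent, which real genes are not. They also had no 0-read value and no shrinkage of low counts, so these rates may not hold for the real genes. Alternatives run were no filter, an adjusted p under 0.1, a test against a 1.2-fold change, the replicate number as a block, and leaving out each library. Chosen after seeing the data were a stricter filter, median centring, quantile normalization, robust spread, library weights, the matched random lists and the Reactome sets. Numbers of genes past the threshold with robust spread and with quantile normalization were already known when these were added.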

Results

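Microglia, the resident macrophages of the brain, were profiled by polyA RNA sequencing in mouse pups at postnatal day 8. The question was what loss of the transcription factor STAT3 in these cells changes in the early postnatal forebrain. Each of the 5 libraries came from CD11b-positive, propidium iodide-negative cells sorted from a pool of 2 to 4 pups of both sexes and 1 genotype. The conditional knockout group held 3 libraries from pups with a tamoxifen-inducible Cre recombinase at Cx3cr1 and floxed Stat3. The control group held 2 libraries from littermates with floxed Stat3 and no Cre. Values were log2 expression centred per gene, so differences between libraries can be read and levels cannot. The depth of each library is unknown, because the values hold no counts. Among the 9400 tested genes, at most 7808 lay above the value given to 0 reads in control replicate 1. The number was at most 8174 in control replicate 2 and at most 8399 to 8424 in the libraries labelled knockout. Only genes found at that value in 3 libraries were taken out. Genes at it in fewer libraries therefore still count as above it. Both controls, and no other library, lay at that value for 411 tested genes (4.4%), against at most 241 for the 5 other pairs of libraries in which this can be recognised. The first principal component (37.6%) set control replicate 1 apart and the next (25.4%) control replicate 2.

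Stat3 was not lower in the libraries labelled knockout, while Cx3cr1, the fractalkine receptor gene that carries the Cre insertion, was lower in each of them than in both controls. Stat3 lies on chromosome 11 from 100885098 to 100939540, and Cx3cr1 on chromosome 9 from 119901616 to 120069879 (GRCm38). Stat3 stood at 0.96, 0.07 and 0.24 in the libraries labelled knockout and at 0.08 and 0.45 in the controls. The means were 0.43 ± 0.47 (SD, n = 3) and 0.26 ± 0.26 (SD, n = 2), a log2 difference of 0.17 with SE 0.42 and a 95% interval from -0.79 to 1.12. The limma adjusted p was 0.947. The difference turned to -0.10 without knockout replicate 1, -0.02 without control replicate 1, -0.08 with libraries centred on their median and -0.02 with quantile normalization. Cx3cr1 averaged 3.23 ± 0.20 (SD, n = 3) against 4.13 ± 0.26 (SD, n = 2), a log2 difference of -0.90 with SE 0.37 and a 95% interval from -1.75 to -0.05. Its adjusted p was 0.638 over all tested genes and 0.0804 over this pair of genes alone, so it did not pass. The Stat3 value is given per gene and was taken to include exons outside the floxed part, although how reads were counted is not given. It therefore checks the labels only weakly. Because Stat3 showed no clear difference and so does not bear out the labels, directions below are given for the libraries labelled knockout.

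**Figure D1:**
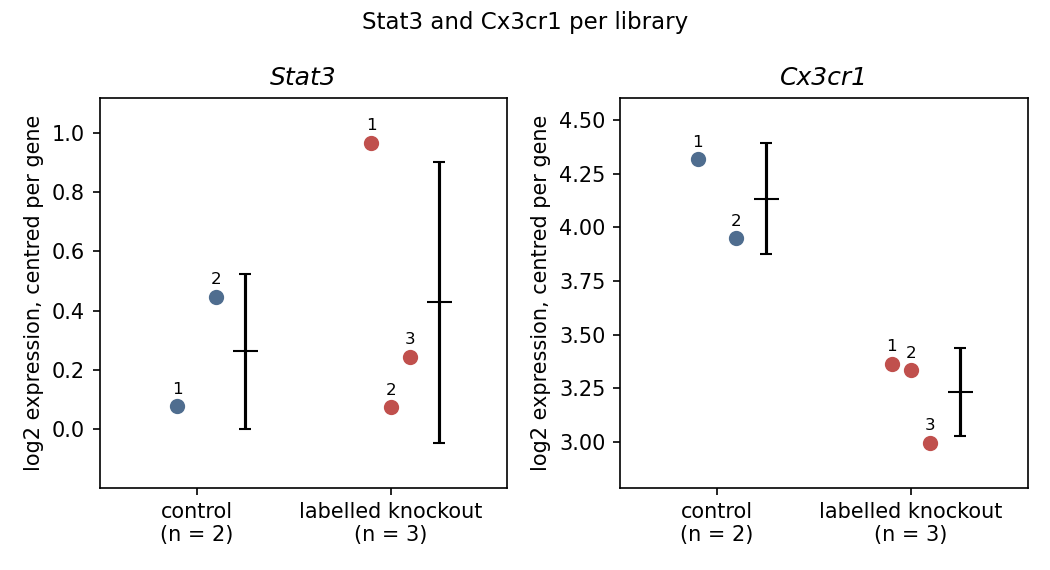
Expression of Stat3 and Cx3cr1 in each library, on a log2 scale centred per gene. Points are libraries with their replicate numbers, and the black bars are the group mean and SD. Stat3 overlaps between the groups, and the 3 libraries labelled knockout lie below both controls for Cx3cr1.

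No single gene passed the threshold in the comparison of the libraries labelled knockout with the controls. The genes that stood farthest apart included S100a9, a subunit of the neutrophil protein calprotectin, the integrin Itgal, the complement receptor C5ar1 and the cytokine Tnf. All were higher in each library labelled knockout than in both controls. Sord, which encodes sorbitol dehydrogenase, the aminoacylase Acy1 and the stress-response gene Gadd45g stood apart in the other direction. With limma, 0 genes were higher and 0 lower at the adjusted threshold, and the smallest adjusted p was 0.565. At an unadjusted p under 0.05, 526 genes were higher and 198 lower, 724 in all against 470 expected by chance. Each library labelled knockout lay above both controls for 17.2% of genes and below both for 7.1%, where chance gives 10% in each direction. The share above includes ties. For 316 genes, knockout replicate 1 and both controls were found at the 0-read value, which the transform sets slightly highest in knockout replicate 1. Such genes can count as above without more reads in that library, so the shares above and below are not on equal terms. Both directions together made 2280 genes, such ties included, and grouping knockout replicate 3 with control replicate 2 against the rest separated 2297. These counts depended on scaling and on 1 library: they were 204 higher and 425 lower with libraries centred on their median, 302 and 301 with quantile normalization, and 685 and 445 without control replicate 2. Over all tested genes the median log2 difference was 0.14, and list medians below are given relative to it.

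The genes with the smallest p on the higher side included S100a9, Itgal, Foxo4, H2-Q4, Myo1g, C5ar1, Ifit2, Rgs1 and Tnf, none of which passed. S100a9 averaged 2.11 ± 0.33 (SD, n = 3) and stood at -0.33 and -0.37 in the controls. Itgal averaged 1.80 ± 0.29 (SD, n = 3) against -0.28 and -0.32. H2-Q4, a class I histocompatibility gene whose paralogs can share 40 bp reads, averaged 2.81 ± 0.38 (SD, n = 3) against 0.47 ± 0.81 (SD, n = 2), and its value is uncertain for that reason. C5ar1 averaged 1.58 ± 0.17 and Tnf 1.51 ± 0.16 (SD, n = 3), against control means of -0.23 and -0.22. In Foxo4 and Ifit2 both controls were found at the value given to 0 reads, with control SDs of 0.034 and 0.042. The control SDs of S100a9, Itgal, C5ar1, Rgs1 and Tnf were no wider, from 0.018 to 0.029. Their controls may lie at that value too, since a pair of libraries at it is harder to recognise. The 10 on the lower side were Sord, Acy1, Eapp, Bola1, Gadd45g, Casc3, Myo15, Klhl22, Pdzd4 and Ash1l, and none of them passed either. Sord stood at 1.73 and 1.74 in the controls and at the 0-read value in all 3 libraries labelled knockout, as did Gadd45g and Myo15. The Ash1l difference was -1.61, and -1.06 without control replicate 1. Acy1 averaged 0.06 ± 0.38 (SD, n = 3) against 1.91 ± 0.03 (SD, n = 2). Without the filter on low values, Sord alone passed (limma adjusted p = 0.00853, within a range from 0.00853 to 0.888 over the alternatives run). That fit held 16423 genes, including those at the 0-read value in 4 or 5 libraries. The Sord difference was -2.017 with and without the filter, so only the spread limma assigned and the adjustment over genes changed.

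Genes of the type I interferon response were higher as a group in the libraries labelled knockout. Of 35 tested members, 32 were higher and 3 lower, and 20 lay above both controls in every library labelled knockout. That number holds ties: in Slfn5, Mx2, Herc6, Mx1 and Oas3, knockout replicate 1 lay at the 0-read value like both controls. It stands above them there only because the transform gives this library the highest 0-read value. In 8 of the 35, both controls and no other library were found at the 0-read value, against 4.4% of tested genes. In 11 more, 3 libraries were at it, and in most of these both controls were among them. Where both controls were at it, the difference sets detected against undetected reads. Ifit2, an interferon-induced RNA-binding protein gene, averaged 1.08 ± 0.24 (SD, n = 3) and stood at the 0-read value in both controls. Oasl2, of the oligoadenylate synthetase family, averaged 1.41 ± 0.63 (SD, n = 3) and stood at that value in both controls too. The median of the list was 0.63 log2 units above that of all tested genes (camera adjusted p = 4.71e-07). It did not pass with an estimated correlation (adjusted p = 0.157 with an estimated correlation), and fry gave an adjusted p of 0.0358, within a range from 8.72e-10 to 0.157 over the alternatives run. The estimated correlation was -0.012, below the preset 0.01, and camera with it gave an unadjusted p of 0.00747. Single members past the threshold numbered 0 over all tested genes and 1 adjusted over the list alone. Monocyte and neutrophil markers, described below, were higher in the same libraries.

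**Figure D2:**
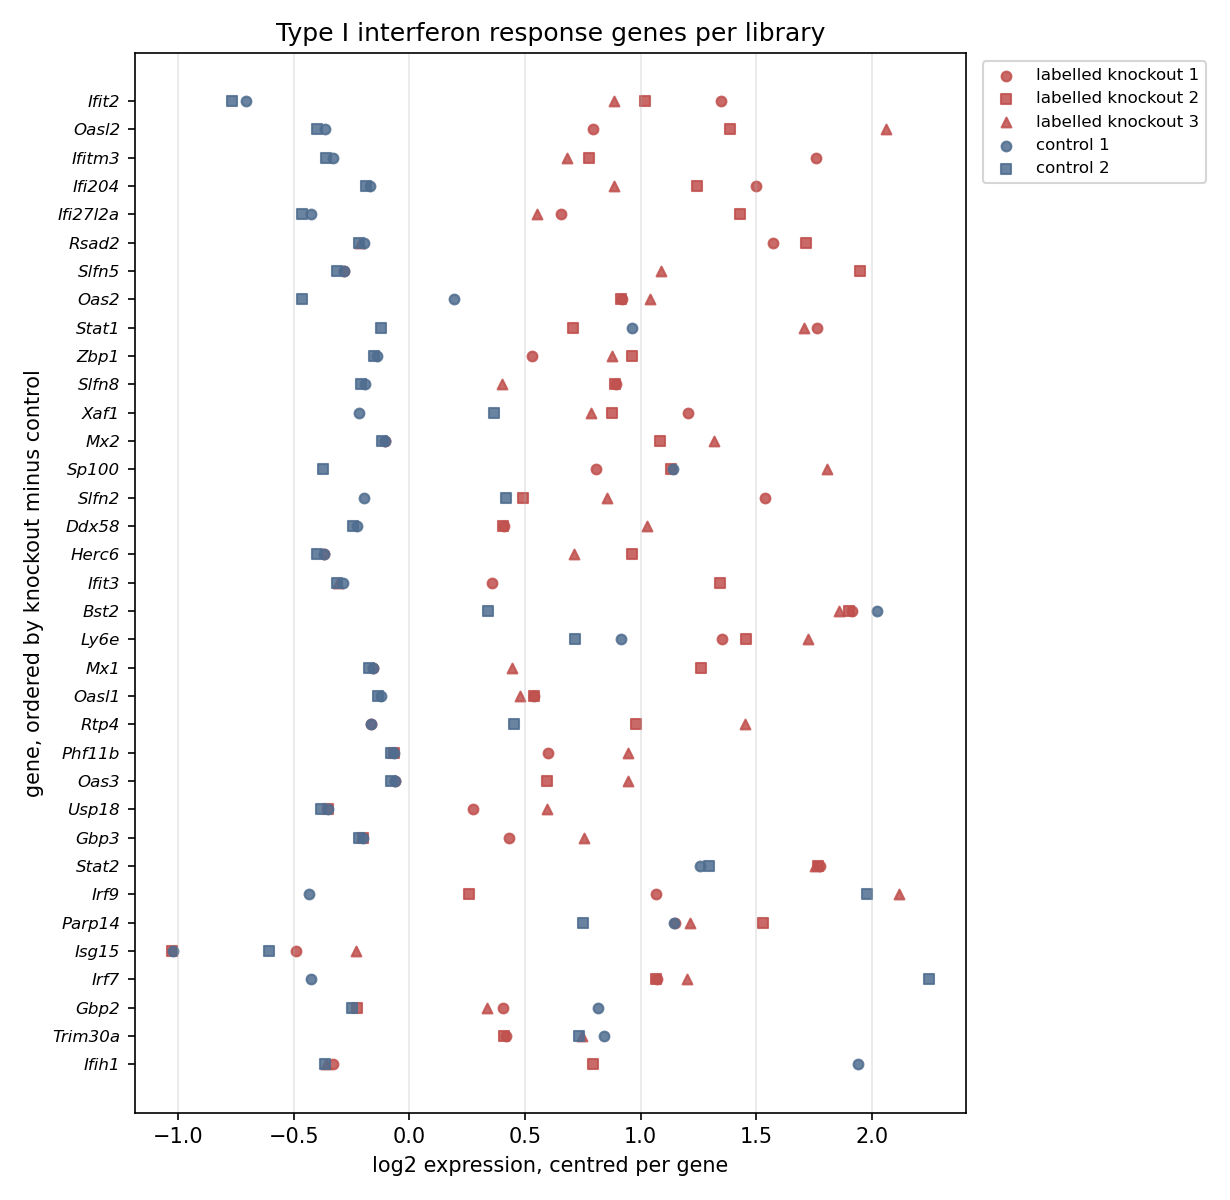
Expression of the 35 tested type I interferon response genes in each library, on a log2 scale centred per gene, with genes ordered by the knockout minus control difference. Red points are the 3 libraries labelled knockout and blue points the 2 controls. In 20 genes every red point lies to the right of both blue points. In Slfn5, Mx2, Herc6, Mx1 and Oas3 among them, knockout replicate 1 lies at the 0-read value like both controls.

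Genes of antigen presentation and of complement and phagocytosis were also higher as groups. In the antigen presentation list 18 of 21 tested members were higher, with a median 0.55 above that of all genes (camera adjusted p = 0.00089, and adjusted p = 0.526 with an estimated correlation). H2-D1, a classical class I gene, averaged 2.64 ± 0.51 (SD, n = 3) against 1.05 ± 0.26 (SD, n = 2), and shares sequence with its paralogs. H2-DMb1, which helps load class II molecules, averaged 1.24 ± 0.25 (SD, n = 3) and lay at the 0-read value in both controls. In the complement and phagocytosis list 32 of 42 tested members were higher, with a median 0.28 above that of all genes (camera adjusted p = 0.0155, and adjusted p = 0.609 with an estimated correlation). Its leading members were C5ar1 and C3, the central complement component, which averaged 1.89 ± 0.22 (SD, n = 3) against 0.00 ± 0.46 (SD, n = 2). Members past the threshold over all genes numbered 0 in both lists. Adjusted over the list alone they numbered 0 for antigen presentation and 2 for complement and phagocytosis. Without control replicate 1 neither list passed (camera adjusted p = 0.0539 and 0.502), and without knockout replicate 1 the complement list did not (adjusted p = 0.0941). Over the alternatives run the adjusted p ranged from 2.67e-05 to 0.526 for antigen presentation and from 0.000229 to 0.609 for complement and phagocytosis. The complement median was 0.04 without control replicate 1, 0.17 without control replicate 2 and 0.15 without knockout replicate 3, and the antigen presentation median was 0.93 without knockout replicate 2. Markers of monocytes and neutrophils were higher in the same libraries.

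Markers of monocytes and neutrophils, blood cells that also carry CD11b, were higher as groups in the libraries labelled knockout. All 11 tested monocyte markers were higher, with a median 0.71 above that of all genes (camera adjusted p = 0.00351, and adjusted p = 0.609 with an estimated correlation). Treml4 averaged 0.84 ± 0.24 and the chemokine receptor gene Ccr2 0.81 ± 0.29 (SD, n = 3), with both controls at the 0-read value. Of 8 tested neutrophil markers 7 were higher, with a median 0.62 above that of all genes (camera adjusted p = 0.00883, and adjusted p = 0.609 with an estimated correlation). S100a9 and lactoferrin (Ltf) led this list, and Ltf averaged 1.21 ± 0.40 (SD, n = 3) against 0.12 ± 0.45 (SD, n = 2). Members past the threshold over all genes numbered 0 in both lists. Adjusted over the list alone they numbered 0 for monocytes and 1 for neutrophils. Neither list passed without control replicate 1 (camera adjusted p = 0.256 and 0.11) or without knockout replicate 1 (0.0567 and 0.0941), and the neutrophil list did not pass without control replicate 2 (0.086, with a median of 0.27). Over the alternatives run the adjusted p ranged from 0.000407 to 0.609 for monocytes and from 0.00152 to 0.609 for neutrophils. The lists past the threshold numbered 5, but 1 without control replicate 1 and 2 without knockout replicate 1. Setting knockout replicates 1 and 3 against the other libraries also put 5 lists past it, and knockout replicates 2 and 3 against the others 2.

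Lists tied to STAT3 itself and to microglial identity did not pass. Among the JAK-STAT components 18 of 30 tested members were higher (camera adjusted p = 0.974), with a median 0.02 above and a mean 0.05 below that of all genes, and the test pointed down. Stat5b and Csf2rb had the smallest p in that list, with log2 differences of 0.85 and 1.15. Of 31 tested STAT3 target genes 21 were higher (median 0.04, adjusted p = 0.989), led by Fgl2 at 1.33 and Bcl2 at 0.87. In the homeostatic microglia list 18 of 33 members were higher (median -0.09, adjusted p = 0.827). The leading members of that list were Mef2a at 0.99 and Siglech at -0.92. The postnatal and disease-associated microglia list had 23 of 33 members higher (median 0.10, adjusted p = 0.361), led by Ccl4 at 1.72 and Vim at 1.62. For inflammatory cytokines and NF-kB 17 of 28 members were higher (median 0.28, adjusted p = 0.47), led by Tnf and Ccl4, with 2 members past the threshold adjusted over the list alone. Trophic and anti-inflammatory factors had 7 of 13 higher (median -0.04, adjusted p = 0.683), led by Pdgfb at -0.77 and Gdf15 at -0.62. Some medians turned direction: JAK-STAT without knockout replicate 1 (-0.09), knockout replicate 2 (-0.07) or control replicate 2 (-0.09), STAT3 targets without knockout replicate 1 (-0.01) or control replicate 2 (-0.10), and trophic factors without control replicate 1 (0.03) or without the filter on low values (0.008). The NF-kB median was 0.10 without knockout replicate 1, 0.12 without knockout replicate 3 and 0.16 without control replicate 2. The homeostatic median was -0.26 without control replicate 2, and turned to 0.066 without the filter on low values and 0.10 with quantile normalization. The postnatal list passed with quantile normalization (median 0.298, camera adjusted p = 0.036, within a range from 0.036 to 0.755 over the alternatives run), and the postnatal median ran from 0.04 without knockout replicate 3 to 0.17 without knockout replicate 1. Among members, Csf2rb was 0.20 without control replicate 1 and 2.11 without control replicate 2, Vim 0.85 without control replicate 2 and Stat5b 0.56 without knockout replicate 3. Bcl2 was 0.51 without knockout replicate 2 and 1.32 without knockout replicate 3, Pdgfb -0.395 without control replicate 2 and Gdf15 -0.34 without knockout replicate 1.

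Growth, stress and metabolic lists did not pass either. For cell cycle 33 of 50 members were higher (median 0.16, camera adjusted p = 0.164), led by Bub1b at 1.28 and Tpx2 at 1.09. It passed without control replicate 2 (adjusted p = 0.0107) and without the filter on low values (0.0239, within a range from 0.0107 to 0.946 over the alternatives run). The immediate early and dissociation list had 19 of 35 higher (median -0.11, adjusted p = 0.554), led by Rgs1 at 1.81 and Rgs2 at 0.84, with 1 member past the threshold adjusted over the list alone. Its median ran from -0.40 without control replicate 2 and -0.316 without knockout replicate 1 to 0.007 without knockout replicate 2 and 0.014 without knockout replicate 3. It turned as well without the filter (0.031) and with quantile normalization (0.002). The replicate block gave 0.014 too, since it yields the same differences as leaving out knockout replicate 3. Lipid and cholesterol metabolism had 17 of 35 higher (median -0.14, adjusted p = 0.679), led by Soat1 at 1.45 and Hmgcs1 at 1.07. Glycolysis had 17 of 22 higher (median 0.15, adjusted p = 0.683), led by Slc16a3 at 1.15 and Ldhb at 0.95. Oxidative phosphorylation had 41 of 61 higher (median 0.07, adjusted p = 0.47), led by Ndufs8 at 1.45 and Atp5e at 1.39. Leaving out 1 library moved these medians: cell cycle from 0.002 without control replicate 1 to 0.295 without control replicate 2, glycolysis from 0.018 without knockout replicate 1 to 0.229 without knockout replicate 2, and oxidative phosphorylation from 0.025 without control replicate 1 to 0.277 without control replicate 2. Lipid metabolism ran from -0.257 without control replicate 1 to -0.086 without knockout replicate 3. Bub1b was 0.74 and Ldhb 0.63 without control replicate 1, and Slc16a3 was 0.76 without control replicate 2. In every list of this paragraph and the one before, 0 members passed over all tested genes, and adjusted over the list alone 0 passed except where stated.

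**Figure D3:**
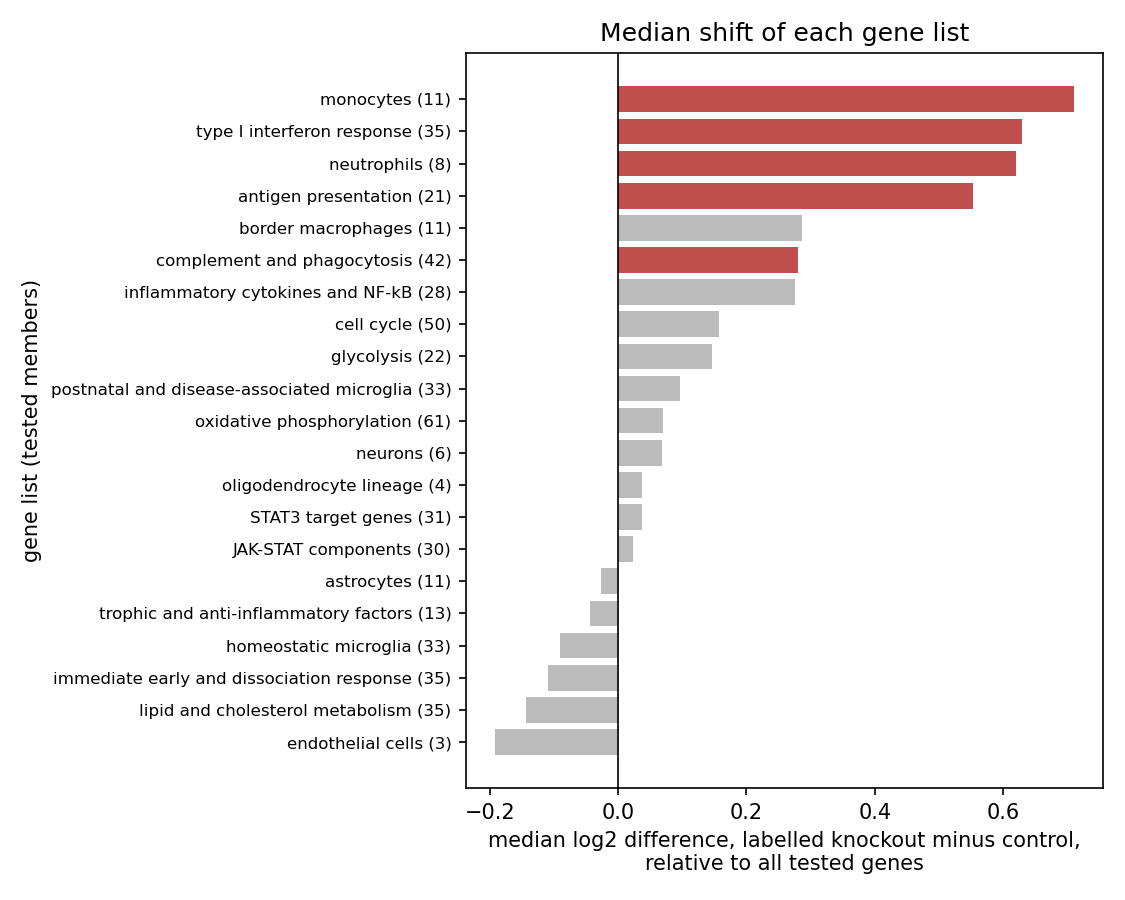
Median log2 difference of each tested gene list, knockout minus control, relative to the median of all tested genes, with the number of tested members in brackets. Red bars passed camera at the adjusted threshold with the preset correlation, and grey bars did not. With an estimated correlation 0 lists passed. The 5 red bars run from 0.28 for complement and phagocytosis to 0.71 for monocytes.

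Markers of the other cell types a forebrain sort could hold did not pass. Border macrophage markers had 8 of 11 members higher (median 0.29, camera adjusted p = 0.47), led by Pf4 at 0.96 and Cd163 at 1.08. Neuronal markers had 5 of 6 higher (median 0.07, adjusted p = 0.827), led by Stmn2 at 0.51 and Celf4 at 0.25. Astrocyte markers had 6 of 11 higher (median -0.03, adjusted p = 0.989), led by Fgfr3 at 0.63 and Sparcl1 at 0.55. Oligodendrocyte lineage markers had 2 of 4 higher (median 0.04 and mean 0.07, with the test pointing down, adjusted p = 0.989), led by Cnp at 1.26 and Bcas1 at -0.79. Endothelial markers had 1 of 3 higher (median -0.19, adjusted p = 0.974), led by Pecam1 at 0.60 and Kdr at -0.71. Lymphocyte, mural and fibroblast, and red blood cell lists had 1, 2 and 1 tested members and were not tested as lists. Their log2 differences were -0.33 for Cd79b, 0.38 for Igfbp7, -0.37 for Pdgfrb and 0.27 for Alas2. Without knockout replicate 3 the border macrophage median was 0.16, Cd163 0.57, Stmn2 0.28, Fgfr3 0.30 and Sparcl1 0.17, and without control replicate 2 the border macrophage median was 0.14. Igfbp7 was 0.06 and Alas2 0.02 without control replicate 1. Direction turned without 1 library for Cd79b (0.15 without knockout replicate 1), Pdgfrb (0.50 without control replicate 2) and Kdr (0.69 without control replicate 1). Medians turned for neurons without control replicate 2 (-0.13), for oligodendrocyte lineage without knockout replicate 3 (-0.30) or control replicate 2 (-0.11), and for astrocytes without knockout replicate 1 (0.095), knockout replicate 3 (0.013) or control replicate 1 (0.28). The endothelial median turned without knockout replicate 3 (0.007), control replicate 1 (0.50) or control replicate 2 (0.12). With the replicate block the endothelial (0.007), astrocyte (0.013) and oligodendrocyte (-0.30) medians turned, at the same values as without knockout replicate 3. With quantile normalization the neuronal (-0.02) and oligodendrocyte (-0.002) medians turned. With library weights the astrocyte (0.019) and oligodendrocyte (-0.029) ones did, and without the filter the astrocyte one (0.049). Adjusted over the list alone and over all genes, 0 members of these lists passed.

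Sex-linked transcripts varied between the pools, which mixed both sexes. Xist, transcribed from the inactive X chromosome, stood at 0.58, 1.52 and 1.35 in the libraries labelled knockout and at -0.03 and 0.04 in the controls. Tsix overlaps Xist on the opposite strand and cannot be told apart from it here, since the kit does not mark strand. The Y-linked gene Ddx3y stood at 0.44, 0.44 and 0.77 against -0.19 and -0.21, and Eif2s3y at 0.78, 0.77 and 0.65 against 1.56 and -0.62. Kdm5d stood at 0.84, -0.27 and 1.498 against -0.27 and -0.30. For Kdm5d, knockout replicate 2 and both controls lay at the 0-read value. The Ddx3y controls, with an SD of 0.013, may lie at it too. Xist and Ddx3y were both higher in each library labelled knockout than in both controls. None of these genes passed (limma adjusted p from 0.615 to 0.931).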

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

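Alternatives chosen after seeing the data were the stricter filter, median centring, quantile normalization, robust spread and library weights. Alternatives chosen before the data were examined that need counts or levels were not run: other normalizations, a minimum of 5 CPM, DESeq2, voom, a quasi-likelihood fit without robust estimation, another pseudocount and a mean of at least 1. Where 1 control was left out, the lone control was assumed to vary like the other group. The lack of counts limits what can be said of depth. Genes higher numbered 0 under every alternative run, and genes lower numbered 0 except without the filter on low values, where Sord made it 1. Without each library in turn both counts were 0 (0 to 0), and the smallest adjusted p in any of these fits was 0.372. Median centring moved the median difference from 0.14 to -0.11 and genes at an unadjusted p under 0.05 from 526 higher and 198 lower to 204 and 425, and quantile normalization gave 302 and 301.

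The Stat3 difference was -0.08 with median centring and -0.024 with quantile normalization, and ran from -0.10 to 0.35 without each library. Cx3cr1 stayed below 0 under all alternatives run, from -1.08 to -0.72 without each library. Replicate numbers 1 and 2 are shared by the groups, and same-numbered deviations correlated at 0.002 and -0.067. With 2 controls their deviations are mirror images, so these values cannot tell whether same-numbered pools share a litter. No label says that they do. The replicate block called 0 genes and 5 lists, with Stat3 at 0.26 and Cx3cr1 at -0.78. Knockout replicate 3 has no control of the same number, so it adds nothing to these differences, which equal those without it.

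Lists past the threshold numbered 5, and 0 with an estimated correlation, 1 with fry, and 1 to 5 without each library. With an estimated correlation the medians were 0.63 for interferon, 0.28 for complement, 0.55 for antigen presentation, 0.71 for monocytes and 0.62 for neutrophils, as before, and their adjusted p were 0.157, 0.609, 0.526, 0.609 and 0.609. Fry gave 0.172 for the latter 4 at medians of 0.28, 0.55, 0.71 and 0.62. With the stricter filter complement no longer passed (median 0.16, adjusted p = 0.0588). Without each library the medians ran from 0.46 to 0.68 for interferon, which always passed, from 0.038 to 0.195 for complement, 0.39 to 0.93 for antigen presentation, 0.48 to 0.63 for monocytes and 0.27 to 0.89 for neutrophils. The losses came without knockout replicate 1 (complement, monocytes and neutrophils), control replicate 1 (these and antigen presentation) and control replicate 2 (neutrophils).

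Some of the lists that did not pass changed sign. Without the filter medians were 0.066 for homeostatic microglia, 0.008 for trophic factors, 0.031 for immediate early genes and 0.049 for astrocytes. With the block they were 0.014 for immediate early genes, 0.013 for astrocytes, -0.30 for oligodendrocyte lineage and 0.007 for endothelial cells. These are the values without knockout replicate 3 and not a separate result. Quantile normalization gave 0.10 for homeostatic microglia, 0.002 for immediate early genes, -0.02 for neurons and -0.002 for oligodendrocyte lineage, and library weights gave 0.019 for astrocytes and -0.029 for oligodendrocyte lineage. Without each library medians ran from -0.094 to 0.149 for JAK-STAT, -0.10 to 0.14 for STAT3 targets, -0.26 to 0.03 for trophic factors, -0.40 to 0.014 for immediate early genes, -0.13 to 0.14 for neurons, -0.14 to 0.28 for astrocytes, -0.30 to 0.28 for oligodendrocyte lineage and -0.31 to 0.50 for endothelial cells. The causes were not tested. Cell cycle passed without the filter (adjusted p = 0.0239) and without control replicate 2 (0.0107), and the postnatal list with quantile normalization (0.036). Of 711 values of the other 60 named genes under alternatives, 708 kept their direction. The exceptions, without single libraries, were Kdr (-2.099 to 0.687), Cd79b (-0.942 to 0.154) and Pdgfrb (-1.244 to 0.496). Much of this was fixed in advance. Dropping the filter, the stricter filter and robust spread leave differences unchanged, and the replicate block repeats those without knockout replicate 3. The 10 genes per direction were chosen for groups that do not overlap, so leaving out 1 library cannot turn them.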

Other observations

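Tests chosen only after the result was seen were the Reactome sets, the splits for numbers of genes and of lists, and the myeloid marker count. The Cx3cr1 gap and the gene-level Stat3 value were also chosen then. The other tests were fixed after the patterns but before their own results were seen. Among 718 Reactome sets of 10 to 300 tested genes, 2 passed camera and both were higher in the libraries labelled knockout. The set of immunoregulatory interactions between lymphoid and non-lymphoid cells had 23 of 24 genes higher, with a median 0.66 above that of all genes (camera adjusted p = 4.72e-05, and adjusted p = 0.996 with an estimated correlation). By p its first members are the integrin Itgal, the class I gene H2-Q4 and the complement gene C3, with log2 differences of 2.10, 2.34 and 1.89. The set of class I antigen presentation and peptide loading had 19 of 22 genes higher (median 0.57, camera adjusted p = 0.00738, and adjusted p = 0.996 with an estimated correlation), with H2-Q4 and H2-D1 first by p. The sets share 7 genes, and 4 and 7 of their members are on the antigen presentation list, so they are not separate findings. Monocyte and neutrophil markers were higher in the same libraries (18 of 19). Within 10 Mb of Cx3cr1 on chromosome 9, 8 of 79 genes were at an unadjusted p under 0.05 (10.1%), against 7.6% of 8702 others (one-sided Fisher exact p = 0.256). The 8 are Ccr1, Ccr2, Xcr1, Exosc7, Fyco1, Ltf and Plcd1, which were higher, and Cxcr6, which was lower (-1.31). Ccr2 and Ltf are also on the monocyte and neutrophil lists. The test decides nothing either way about flanking DNA. Over the 10 splits of the 5 libraries into 3 and 2, only the real one (1 of 10) gave as many genes at that p, with 724 against at most 609. Numbers of separated genes and of lists go the other way. Another split separated 2297 genes against 2280, and both counts can hold ties at the 0-read value. One more split put as many lists past the threshold as the real one (5). With 10 splits a share under 0.05 cannot be reached.

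The interferon response list was higher at the preset correlation, but did not pass with an estimated correlation (camera adjusted p = 0.157). The estimate was -0.012, below the preset 0.01, so the loss does not show that its members are correlated. Control replicate 1 alone is argued against at the preset correlation, since without that library the list still passed (camera adjusted p = 8.72e-06). Weaker detection of rarely read genes in the controls would move other such genes as well. The list median lay above 100% of 10000 random lists matched on libraries found at the 0-read value. That match is loose, because some such values go unrecognised and read level was not matched, so weaker detection stays open. Chance cannot be judged from 10 splits: the real one alone (1 of 10) had a camera p as small as 2.24e-08, and the next, knockout replicates 2 and 3 against the rest, had 3.41e-07. Blood myeloid cells in the sort, loss of Stat3, loss of 1 Cx3cr1 copy and Cre itself were not tested apart and stay open.

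The higher monocyte and neutrophil lists may reflect cells of another type in the sort, since a CD11b gate would not remove them. That 18 of 19 tested markers were higher restates the pattern and cannot tell such cells from a change of genotype. The median of the joined lists lay above 100% of 10000 matched random lists. That match is loose, because some 0-read values go unrecognised and read level was not matched. Weaker detection of rare genes in the controls therefore stays open. Control replicate 1 alone stays open: without it neither list passed (adjusted p = 0.256 and 0.11), although medians were 0.52 and 0.57 against 0.71 and 0.62 with 1 control fewer. How many of these markers microglia also express was not counted.

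Stat3 was not lower in the libraries labelled knockout, while Cx3cr1 lay below both controls in each of them without passing. A mislabelled library could leave Stat3 not lower but would make Cx3cr1 overlap if the Cre allele lowers it. The gap of 0.585 between the lowest control and the highest library labelled knockout restates the separation, which 7.1% of genes show, so mislabelling stays open. Transcripts that keep the undeleted Stat3 exons may hide the deletion. The gene-level difference of 0.166 cannot tell, because values per exon are not used here. Incomplete recombination was not tested.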
